A study of Mus musculus with 2 samples.

How the data were processed

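The data are total RNA sequencing of embryonic facial prominence from mouse embryos of strain B6NCrl at 11.5 days, 2 libraries in 1 group. Per the labels, library 1 was made from a pool of 109 embryos and library 2 from a pool of 88, both of mixed sex, from 10 ng of RNA longer than 200 nt, with RNA spike-ins added. The labels set no condition against another, so no test between groups was made and no p-value was taken across genes. The library is the unit of replication, and values are given as mean ± SD over the 2 libraries.

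The authors quantified each library against the gene models of GENCODE M4 on assembly mm10, per the notes deposited with the files, from an alignment of the same library to the transcriptome. The column names are those of RSEM, and the version of the aligner and of the quantifier is not given in the sources used here. Per the file headers, expected counts are the reads estimated for each gene or transcript by the authors, with reads that match several places divided among them and no normalization. Per the file headers, TPM, transcript abundance scaled to a fixed total per library, was computed by the authors from these counts and the effective lengths over every entry of a file, spike-ins included. In the deposited transcript files, the isoform percentage gives the share of a gene's TPM that a transcript takes, in percent, as the authors computed it. Posterior mean counts with their SD, posterior mean TPM and bounds of its interval are also deposited, and the level of that interval is not stated, so its bounds were not used here. Strandedness is not given in the sources used here, so levels of genes that overlap others on the opposite strand are uncertain.

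Each file held 43346 genes, 97 spike-in and control sequences and 26248 entries with numeric identifiers of a median length of 73 nt, which were not analysed as genes. Gene symbols, types and positions came from GENCODE M21, on the same assembly, matched on the identifier without its version. This named 42462 genes (98.0%), and the 884 others, which held 0.191% and 0.190% of the counts of library 1 and library 2, kept their identifier. An effective length of 0 was found for 28403 entries under 100 nt, 2218 of them genes, for which no TPM can be computed. Since the RNA was longer than 200 nt per the labels, values of shorter RNAs do not measure their level in the tissue.

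Library 1 held 30849058 expected counts and library 2 held 31600302. A gene with no count was given a limit of 3 counts, which for a transcript of 1 kb is 0.146 TPM in library 1 and 0.144 TPM in library 2. Ratios between the libraries carry the exact 95% Clopper-Pearson interval of the split of the 2 counts. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

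A gene was called detected at 1 TPM or more in both libraries. Before the data were examined, 26 lists with 426 genes were fixed, covering regulators of facial mesenchyme and prominences, signalling pathways, cell types of the dissection and around it, cell state and quality, together with the tests, the rule for named genes and the alternatives. All 426 genes were matched. For each list the number of detected members and the median TPM were taken, with the percentile of that median among 10000 random lists of protein-coding genes of the same size. Ratios between the libraries used expected counts scaled by TMM (edgeR 4.0.16 in R 4.3.3). A prior count of 0.5 entered the log2 ratios of lists and the comparison of sex-linked genes. Folds of other single genes and the 2-fold rule used no prior. The median log2 ratio of each list's members with at least 20 counts was set against 10000 random lists matched on mean expression in 20 bins. A gene was counted as differing at least 2-fold with at least 50 counts over both libraries together and a mean of 1 TPM, which is a rule of size.

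The spread between the libraries was the square root of edgeR's common dispersion, fitted with an intercept alone on counts rounded to whole numbers, over the genes kept by filterByExpr with 1 residual degree of freedom each. A chi-square statistic over genes with at least 10 counts checked that the files are not copies or splits of the same library. A dominant transcript is the one with the largest share of a gene's TPM, compared in genes with at least 2 transcripts and a mean of 10 TPM. Reads were taken as assignable where the posterior SD was at most 10% of the count in both libraries.

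The rule for named genes took the 10 genes with the highest mean TPM. From each list it took the 4 detected members with the highest mean TPM, and for lists of regulators, epithelium, sex chromosomes and signalling also members below 1 TPM in both libraries where these were 5 or fewer. It also took every gene of the Dlx and Alx families, the 10 genes with the largest ratio each way among those with a mean of at least 5 TPM, and, for transcripts, the 6 most abundant genes of the mesenchyme and regulator lists and any of these genes whose dominant transcript differed. Msx2, Tfap2a, Hbb-bh1, Hbb-bs, Pax7, Shh, Ovol1, Ttr, Nkx2-5, Acan and Ibsp were named in addition, after their values were seen. Some genes that the rule takes are not reported here.

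Alternatives covered the detection threshold, posterior means in place of maximum likelihood values, TPM rescaled to nuclear genes without spike-ins and haemoglobins, DESeq2 1.42.0 size factors, library totals and spike-in totals as scaling, the count filters, the prior count, DESeq2's dispersion, the limit on TPM for transcripts, and each library left out. Limits on assignable reads and on the counting interval were added after seeing the data. The steps were tested on simulated data of 2 libraries. The 2-fold rule recovered 99% of 100 genes changed 3-fold and 100% of 100 changed 4-fold, and passed 8 of 13539 unchanged genes. Changed genes were drawn from those with at least 100 counts and a mean of 2 TPM, stricter limits than those of the rule. Every gene had the same spread of 10% and no reads shared with others. These rates therefore do not hold for genes near the limits, with a wider spread or with shared reads. Of 400 unshifted random lists, 22 lay outside the central 95%. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.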

Results

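Total RNA was sequenced from the facial prominences of mouse embryos of strain B6NCrl at embryonic day 11.5. The facial prominences are the swellings around the primitive mouth, made of neural crest mesenchyme under a layer of ectoderm, that grow together into the upper face and the jaws. There were 2 libraries in 1 group, and each was made from its own pool of embryos of both sexes, 109 embryos for library 1 and 88 for library 2. The labels name no treated, mutant or older group, so the data answer which genes this tissue transcribed, at what level, and how far the pools differed from each other. Library 1 held 30849058 expected counts and library 2 held 31600302, of which 28627217 and 29281440 fell on genes. Levels are given in TPM, the abundance of transcripts scaled to a fixed total per library, as mean ± SD over the 2 libraries (n = 2), and positions are on assembly mm10.

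The tissue transcribed a broad set of genes, with the highest values at an annotated non-coding RNA, an embryonic globin gene and genes of mitochondria and cytoskeleton. Of 43346 annotated genes, 13866 reached 1 TPM in both libraries, and they included 12572 of 21474 protein-coding genes (58.5%). Gm42418 (chromosome 17, 39846958 to 39848788), annotated as a long intergenic non-coding RNA, held the highest value at 11295 ± 86.8 TPM. Whether its reads come from such a transcript or from another abundant RNA in total RNA was not tested. Hbb-y, the embryonic beta-like globin, followed at 7094 ± 411, and then mt-Atp6 and mt-Atp8, subunits of the mitochondrial ATP synthase, at 6566 ± 748 and 5698 ± 399. Actb, a cytoskeletal actin, reached 5334 ± 184, the replication-dependent histone gene Hist1h2ap 4674 ± 47.6 and the peptidyl-prolyl isomerase gene Ppia 4560.2 ± 196. The other members of the 10 most abundant genes share sequence with further copies and are uncertain: Gm28437, a nuclear copy of mitochondrial sequence (5845 ± 138), and the signal recognition particle RNA genes Rn7s1 and Rn7s2, which hold identical values (4298 ± 270.3 each). Reads of mt-Atp6 were also shared with such copies, with a posterior SD of up to 17.3% of its count.

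By class, protein-coding genes held 75.9% ± 0.179 of all TPM (SD, n = 2), mitochondrial genes 2.63% ± 0.106, haemoglobin genes 1.69% ± 0.114 and replication-dependent histone genes 0.606% ± 0.00275. The 10 most abundant genes together held 5.97% ± 0.0306. Added RNA spike-ins took 15.6% ± 0.273 of TPM, so every gene's TPM is lower by that share than it would be over mouse transcripts alone. By expected counts the spike-ins held 7.27% and protein-coding genes 88.2%, because TPM weights short transcripts more.

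Genes of neural crest and facial mesenchyme were all transcribed. All 22 members of the mesenchyme list passed 1 TPM in both libraries, with a median of 45.0 TPM against 3.45 over protein-coding genes, a median above those of all 10000 random lists of its size. Vim, the intermediate filament of mesenchyme, led with 541 ± 21.5 TPM, ahead of the fibrillar collagen genes Col3a1 (378 ± 18.8) and Col1a2 (179 ± 11.6). Msx1, a homeobox gene whose loss leaves mice with cleft palate and without teeth, reached 263 ± 20.9 and exceeded its paralog Msx2 by 9.74 ± 1.17 times. Lower members such as Tfap2a, an activator of neural crest genes, still stood at 6.04 ± 0.163.

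The frontonasal list, regulators of the prominence that forms the forehead and nose, was transcribed in full, 10 of 10 members. Its median of 12.7 TPM lay at percentile 85.0 of random lists. Alx1 (ENSMUSG00000036602.9, chromosome 10, 102998707 to 103030215), a homeobox gene required for formation of the upper face, stood highest at 131 ± 14.1 TPM. Its relative Alx4 was lower at 12.9 ± 0.346, so that Alx1 exceeded Alx4 by 10.2 ± 0.822 times. Pax6, the regulator of eye and nasal placode, averaged 15.2 ± 6.72 but was 1.77-fold (1.58 to 1.98) higher in library 1, and Tfap2c, expressed in ectoderm and neural crest, averaged 13 ± 0.750.

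Regulators of the maxillary and mandibular parts of the first pharyngeal arch were likewise all transcribed, 16 of 16. Their median of 11.1 TPM lay at percentile 87.4 of random lists. Barx1 (chromosome 13, 48662998 to 48666507), a homeobox gene of the molar-forming mesenchyme, led with 80.8 ± 34.1 TPM, and its libraries differed, with 56.6 in library 1 and 105 in library 2. Lhx8, a LIM homeobox gene of maxillary mesenchyme, reached 48.3 ± 9.43, the hindlimb and mandibular regulator Pitx1 38.7 ± 3.27 and Osr2, needed for palate growth, 32.7 ± 3.66. All 6 Dlx genes, which pattern the arches along their dorsal to ventral axis, were detected, with a list median at percentile 79.4. Dlx1 and Dlx5 stood highest at 48.8 ± 11.7 and 44.5 ± 4.86, followed by Dlx2 at 14.5 ± 1.21, Dlx3 at 14.2 ± 3.0, Dlx6 at 3.13 ± 1.00 and Dlx4 at 2.48 ± 0.290. Most of Dlx1's TPM was assigned to a pair of retained-intron transcripts, 46.6% and 46.3% in library 1 and 40.1% and 51.1% in library 2, so its rank among the Dlx genes is uncertain. Dlx5 exceeded its neighbour Dlx6 by 14.7 ± 3.17 times.

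**Figure D1:**
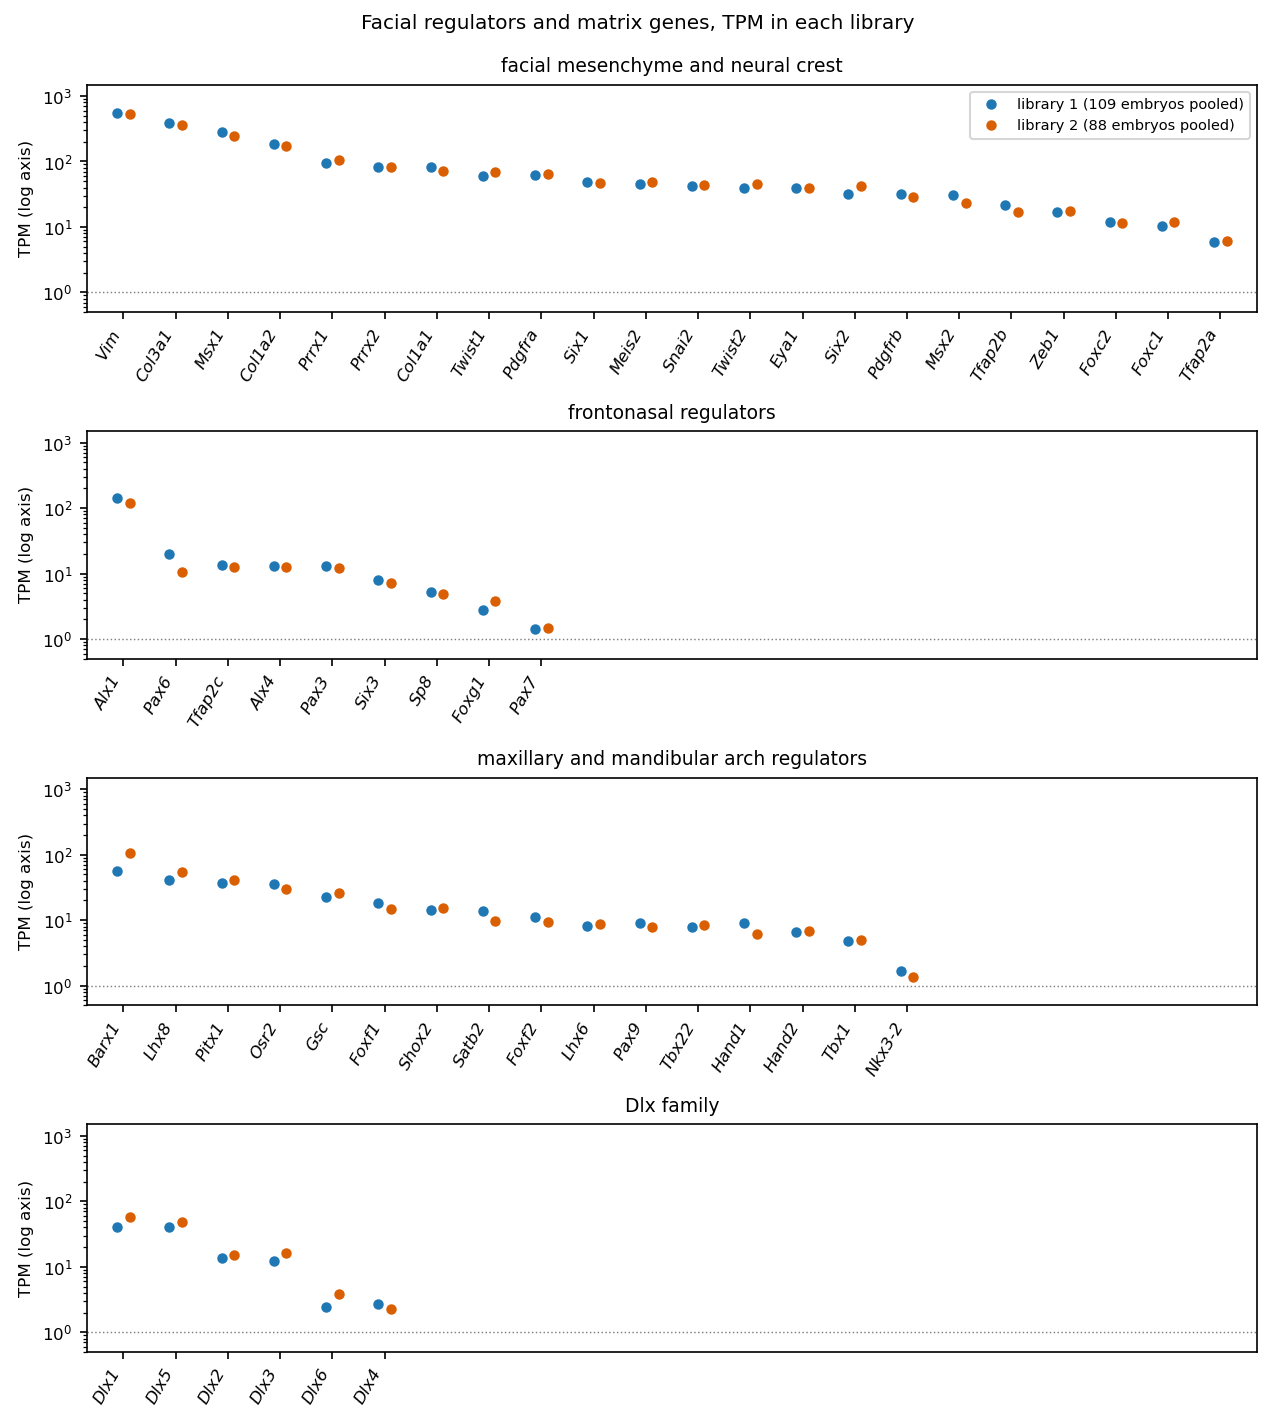
TPM on a log axis of members of the mesenchyme, frontonasal, arch and Dlx lists, with 1 point per library and a dotted line at 1 TPM. All members shown lie above the line in both libraries, from Vim at 541 ± 21.5 TPM down to Pax7 at 1.44 ± 0.0566.

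Hox genes, which specify position behind the jaws and are silent in first-arch crest, were mostly below detection. Only 4 of 39 reached 1 TPM in both libraries, 33 stayed below it in both, and the list's median was 0.245 TPM. The exceptions were Hoxa2, the selector gene of the second arch, at 16.9 ± 2.55, its paralog Hoxb2 at 5.53 ± 1.14, Hoxd3 at 2.12 ± 0.127 and Hoxc4 at 1.25 ± 0.0283. Among the 16 genes of groups 9 to 13, the posterior end of the clusters, none exceeded a mean of 0.380 TPM. For 10 Hox genes no count was recorded in either library, which allows up to 0.157 TPM per library at the limit of 3 counts.

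**Figure D2:**
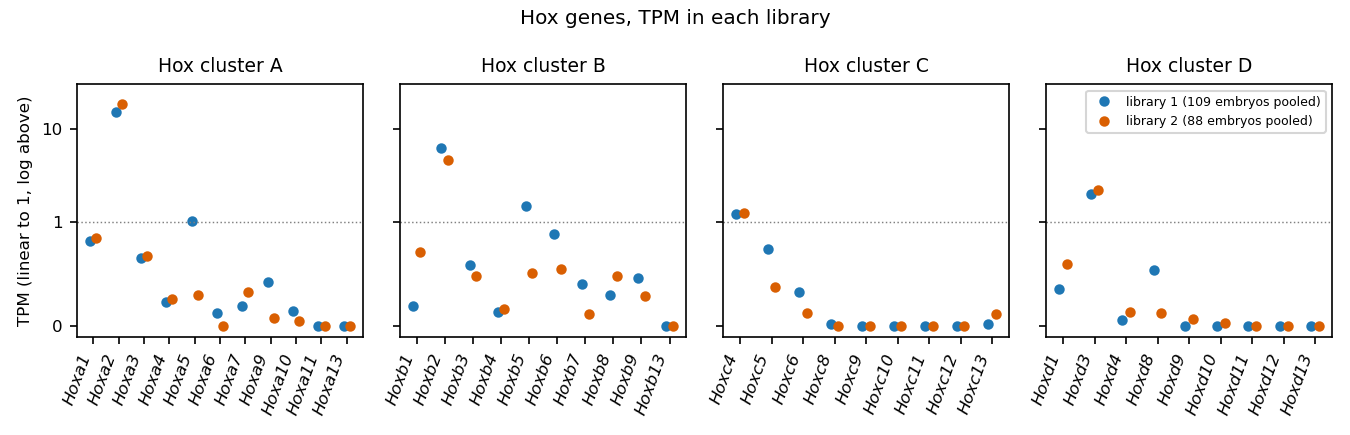
TPM of the Hox genes by cluster and position, with 1 point per library, a dotted line at 1 TPM, and an axis that is linear up to 1 and logarithmic above. Hoxa2 at 16.9 ± 2.55 TPM is the highest point of the 4 clusters, and the posterior genes lie near 0.

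The ectoderm was represented by 21 of 22 epithelial genes, at a median of 13.5 TPM. Epcam, an epithelial adhesion molecule, reached 54.2 ± 3.06 TPM, the simple-epithelium keratin genes Krt18 and Krt8 51.4 ± 9.77 and 41.6 ± 3.25, and the tight junction gene Cldn6 37.9 ± 3.13. Ovol1, a regulator of epidermal differentiation, was at 1.06 and 0.480 TPM and was the member that missed the threshold in a library.

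Listed genes of signalling pathways of facial outgrowth were nearly all detected. Among random lists, the median of the Hedgehog list lay at percentile 86.4, FGF at 83.9, BMP at 82.6 and WNT at 90.1. All of these lie inside the central 95%, while the endothelin and retinoic acid list lay above it at 99.85. All 13 Hedgehog members were detected, with the co-receptor gene Gas1 at 116 ± 3.12 TPM, the transducer Smo at 35.5 ± 1.39, the negative regulator Sufu at 25.5 ± 2.09 and the transcription factor Gli3 at 24.1 ± 0.276, while the ligand Shh itself stood at 1.83 ± 0.728. Of the FGF list, 16 of 17 were detected. The feedback phosphatase gene Dusp6 led with 87.2 ± 3.56, followed by the receptors Fgfr2 (63.9 ± 9.33) and Fgfr1 (56.6 ± 1.58) and the antagonist Spry2 (34.3 ± 5.74), and Fgf3 was below 1 TPM in both libraries at 0.615 ± 0.205. Of the BMP list, 18 of 19 were detected, led by the BMP target genes Id3 (476 ± 25.9), Id2 (431 ± 12.4) and Id1 (130 ± 6.84) and the receptor Bmpr1a (58.0 ± 4.04).

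Of the WNT list, 17 of 19 were detected, with the secreted antagonist Sfrp2 at 140.3 ± 28.4 TPM, the nuclear effector Lef1 at 60.9 ± 6.36, the ligand Wnt5a at 50.8 ± 0.608 and Sfrp1 at 33.1 ± 3.53. Wnt3a was below 1 TPM in both libraries at 0.435 ± 0.205. All 20 endothelin and retinoic acid genes were detected, at a median of 30.4. The retinoic acid binding protein genes Crabp1 (753 ± 42.0) and Crabp2 (478 ± 7.01) stood far above the receptor Rarg (52.1 ± 1.30).

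Markers of the other cell types that a dissected prominence holds were present in both libraries. Erythroid genes reached the highest single levels, with all 16 detected. After Hbb-y came Hba-a2 (3749 ± 333), the embryonic alpha-like globin gene Hba-x (1823 ± 213) and Hba-a1 (1772 ± 127). Hba-a1 and Hba-a2 are near-identical copies, and the posterior SD was at most 0.938% of the count of Hba-a1 and 0.426% of that of Hba-a2. Hbb-y exceeded Hbb-bh1, the other embryonic beta-like globin gene, by 4.04 ± 0.221 times and the adult gene Hbb-bs by 72.4 ± 0.827 times. All 15 endothelial genes were detected, led by Egfl7 (48.9 ± 11.0), a factor secreted by endothelium, the diaphragm protein gene Plvap (36.9 ± 0.742), Emcn (27.8 ± 1.07) and the adhesion gene Esam (22.4 ± 3.71). Of 17 white blood cell genes, 15 were detected, led by the platelet and macrophage chemokine gene Pf4 (51.5 ± 4.86), the complement gene C1qb (22.9 ± 1.68), Laptm5 (18.7 ± 0.0849) and Fcer1g (15.8 ± 1.16).

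Neuronal genes were all detected, 18 of 18, at a median of 26.8 TPM. The neuronal tubulin gene Tubb3 stood at 168 ± 26.5, the growth cone gene Gap43 at 119.9 ± 7.13, Stmn2 at 86.5 ± 6.51 and the neurofilament gene Nefl at 77.7 ± 12.4. All 17 genes of forebrain, eye and olfactory epithelium were detected, with the radial glia gene Fabp7 at 173 ± 14.8, the lens crystallin gene Cryaa at 65.4 ± 74.3, the pigment granule gene Pmel at 36.1 ± 21.1 and Ebf2 at 27.6 ± 1.78. For Cryaa the SD exceeded the mean, with 118 TPM in library 1 and 12.9 in library 2, and Pmel stood at 51.0 and 21.2. Of 9 genes of glia and Schwann precursors, 7 were detected, and among them, beside Fabp7, were the endothelin receptor Ednrb (26.8 ± 1.91) and Sox10 (8.86 ± 0.552), the regulator of glial and pigment lineages.

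Genes of muscle and cartilage were transcribed, while several genes of mature cartilage and bone were not detected. Of 14 skeletal muscle genes, 12 were detected, led by the cardiac and embryonic actin gene Actc1 (65.2 ± 30.9), the slow troponin gene Tnnt1 (40.0 ± 8.71), the myogenic regulator Myog (13.2 ± 2.40) and the myosin light chain gene Myl1 (11.1 ± 3.38). Of 16 cartilage and bone genes, 11 were detected. The early cartilage genes Col2a1 (129 ± 8.33), Sox9 (69.7 ± 0.806), Col9a1 (36.6 ± 5.13) and Sox5 (17.5 ± 2.09) led, and 5 members, among them the cartilage proteoglycan gene Acan and the bone matrix gene Ibsp, stayed below 1 TPM in both libraries. Of 16 heart and liver genes, listed as tissues outside the dissection, 8 were detected at a list median of 1.42. These were led by the transferrin gene Trf (21.5 ± 0.573) and by Myl2 (19.9 ± 12.4), Myl7 (12.4 ± 9.45) and Nppa (8.07 ± 9.35), listed for heart, whose libraries lay far apart.

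Genes of the cell cycle were high throughout, 18 of 18 detected at a median of 199 TPM. The mitotic kinase gene Cdk1 stood at 381 ± 0.255, the spindle gene Birc5 at 323 ± 12.5, the topoisomerase gene Top2a at 314 ± 21.6 and Pcna, the DNA polymerase clamp, at 305 ± 20.5. Imprinted genes, many of which control embryonic growth, were also high, 19 of 19 at a median of 147, led by Mest (1426 ± 32.8), Nnat (1140.1 ± 35.7), the cell cycle inhibitor gene Cdkn1c (615 ± 14.6) and H19 (252 ± 10.8). Of the hypoxia and glycolysis genes, 14 of 15 were detected, with the glycolytic genes Ldha (1253 ± 114), Aldoa (482 ± 35.5) and Pgk1 (315 ± 14.4) and the glucose transporter gene Slc2a1 (99.4 ± 17.8) highest.

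Of the immediate early and stress genes, which dissection can induce, 11 of 15 were detected. Their median of 1.89 TPM lay at percentile 34.8 of random lists, so the list was neither high nor low against them. Highest were Ier2 at 66.6 ± 1.68, Btg2 at 29.0 ± 0.332, Jun at 25.8 ± 1.44 and Dusp1 at 19.9 ± 1.20. RNAs that lack a poly(A) tail or stay in the nucleus were detected for 6 of 12, with Malat1 at 1387 ± 124, the 7SK RNA gene Rn7sk at 148 ± 32.3, the RNase P RNA gene Rpph1 at 48.5 ± 2.01 and Rmrp at 22.3 ± 1.60. Of 9 sex chromosome genes, 6 were detected in these pools of both sexes, with the Y-linked genes Eif2s3y (21.5 ± 1.06), Ddx3y (16.7 ± 2.40) and Kdm5d (10.2 ± 1.68) beside Xist (16.1 ± 2.56), the RNA that silences an X chromosome in females. The testis-determining gene Sry and Zfy1 had no count in either library, which allows up to 0.134 TPM for Sry and 0.0537 TPM for Zfy1 in library 1, and Usp9y had a mean of 0.00500 ± 0.00707.

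The 2 libraries gave closely matching levels. Across the 13866 detected genes Pearson's r of log2(TPM + 1) was 0.993, a correlation across genes, which are not independent replicates, and 95% of the genes lay within 1.5-fold. The libraries are separate pools per the labels, and their counts were not copies of each other, with a chi-square of 8.35 per degree of freedom over 18131 genes. The coefficient of variation between the pools beyond counting error, from edgeR's common dispersion over 16002 genes, was 9.80%. DESeq2's median gene-wise estimate was lower at 2.99%, and on counts simulated at 10% the same estimate gave 3.55% where edgeR gave 10.0%.

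Tissue markers differed between the pools in both directions. The medians of 11 of the 26 lists, library 2 over library 1, lay outside the central 95% of 10000 random lists matched on expression. By chance 1.30 would do so if genes varied independently. Members of a tissue list can move together, so 1.30 is not the number expected between 2 ordinary pools. The count describes these 2 libraries and is no test of a condition. Neuronal genes had a median ratio of 1.18-fold toward library 1, where 15 of 18 members had an interval that excluded 1, among them Tubb3 at 1.23-fold (1.19 to 1.27) and Nefl at 1.23-fold (1.19 to 1.28), with the 95% Clopper-Pearson interval of the ratio in brackets. Skeletal muscle genes had a median ratio of 1.42-fold toward library 2, where 10 of 13 measured members had an interval that excluded 1, with Actc1 at 2.04-fold (1.91 to 2.19), Tnnt1 at 1.39-fold (1.25 to 1.55) and Myog at 1.32-fold (1.14 to 1.53). Such intervals hold counting error and not the spread between pools, and the share of all genes whose interval excludes 1 is not given here. Counts of members of this kind, here and below, therefore do not by themselves set a list apart.

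Beside neurons, the lists of forebrain, eye and olfactory genes, endothelium, surface epithelium, erythroid cells, endothelin and retinoic acid signalling and imprinted genes lay below the random range. Their median log2 ratios were -0.22, -0.20, -0.14, -0.14, -0.09 and -0.05. Egfl7 was 1.38-fold (1.25 to 1.52), Krt18 1.29-fold (1.19 to 1.39) and Hba-x 1.15-fold (1.13 to 1.17) higher in library 1. Above the range, beside skeletal muscle, lay the lists of heart and liver (median log2 ratio 0.99), the Dlx family (0.35) and the sex chromosomes (0.25). Of the Dlx genes, Dlx1 was 1.5-fold (1.41 to 1.60) and Dlx3 1.38-fold (1.24 to 1.53) higher in library 2, while Dlx4 had a ratio of 0.884. In the heart and liver list Myl2 was 3.09-fold (2.47 to 3.89) and Myl7 3.38-fold (2.51 to 4.61) higher in library 2, whereas the cardiac regulator Nkx2-5 had a ratio of 0.816 (0.524 to 1.26), the liver gene Trf had a ratio of 1.02 and Ttr, a transport protein of choroid plexus and liver, was 4.84-fold (3.40 to 7.06) higher in library 1. The intervals cover counting error only.

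The mesenchyme list lay inside the range at 0.01, as did the frontonasal (-0.09) and arch (0.02) regulators, Hox genes (-0.05), white blood cells (-0.12), glia (-0.02) and cartilage and bone (-0.09). Signalling lists inside the range were Hedgehog (-0.07), FGF (-0.08), BMP (0.05) and WNT (-0.05). The cell cycle (0.09), stress (-0.19), hypoxia (-0.07) and nuclear RNA (-0.05) lists were inside it too.

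**Figure D3:**
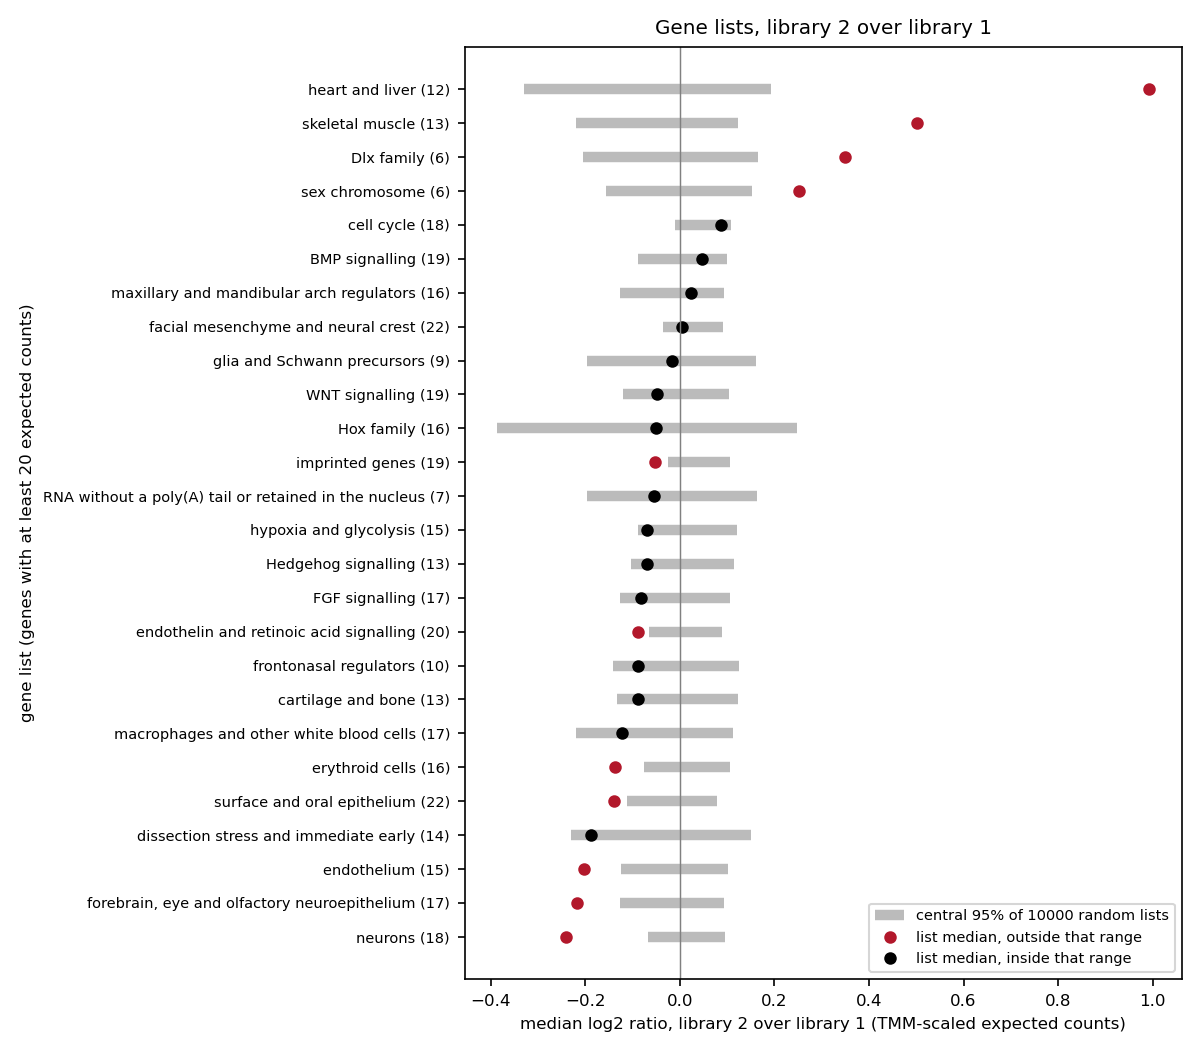
Median log2 ratio of each gene list, library 2 over library 1, from TMM-scaled expected counts (points), with the central 95% of the medians of 10000 random lists matched on expression (grey bars) and the number of genes in brackets. The heart and liver list at 0.99 and the neuron list at -0.24 are the extremes.

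The genes with the largest ratios between the pools included lens crystallin genes, higher in library 1, and sarcomere genes used by heart, higher in library 2. Some of these sarcomere genes are also used by skeletal muscle, whose list was higher in library 2 too. Of 13739 genes with at least 50 expected counts and a mean of 1 TPM, 184 (1.34%) differed at least 2-fold, 116 higher in library 1 and 68 higher in library 2. The lens crystallin gene Cryaa (ENSMUSG00000024041.8, chromosome 17, 31677807 to 31681733) stood at 118 TPM in library 1 and 12.9 in library 2, a ratio of 9.01-fold (7.98 to 10.2). Further crystallin genes went the same way, Crybb1 by 7.37-fold (5.11 to 10.9), Crybb3 by 5.92-fold (4.17 to 8.63) and Cryba1 by 5.56-fold (4.55 to 6.85), and so did Aldh1a1, a retinaldehyde dehydrogenase gene of the dorsal retina, by 2.78-fold (2.55 to 3.03). Higher in library 2 were Nppa (ENSMUSG00000041616.9, chromosome 4, 148000722 to 148002079), the atrial natriuretic peptide gene, at 1.46 against 14.7 TPM and a ratio of 10.2-fold (6.64 to 16.4), and the sarcomere genes Myl3 by 4.97-fold (3.48 to 7.28), Myl4 by 3.77-fold (2.76 to 5.22), Myl7 by 3.38-fold (2.51 to 4.61), Tnnt2 by 3.40-fold (2.58 to 4.52) and Myl2 by 3.09-fold (2.47 to 3.89).

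Outside muscle, Cnpy1, a gene of the boundary between midbrain and hindbrain that promotes FGF signalling in zebrafish, was 4.27-fold (3.47 to 5.29) higher in library 2, and Rab21, a small GTPase gene of endosomes, was 2.9-fold (2.46 to 3.43) higher. The remaining genes with the largest ratios had reads that could not be assigned with certainty, with a posterior SD above 10% of the count. These were Gm10925, Gm6505, Gm28592 and ENSMUSG00000103057.1, higher in library 1 by 3.68, 2.80, 2.80 and 9.04 times, and mt-Nd4l and Gm13394, higher in library 2 by 6.08 and 5.86 times. Gm15899 stood at 24.4 TPM in library 1, with a posterior SD as large as its count, and had no count in library 2, so no fold is given. With 1 library on each side the rule is one of size and has no replicate check. The interval of the ratio lay beyond 2-fold as a whole for 63 of the 184 genes, 30 higher in library 1 and 33 higher in library 2. These 63 showed no excess toward library 1, but they include genes whose reads were not assignable. Among the 129 of the 184 genes with assignable reads the excess remained, with 88 higher in library 1 and 41 in library 2.

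**Figure D4:**
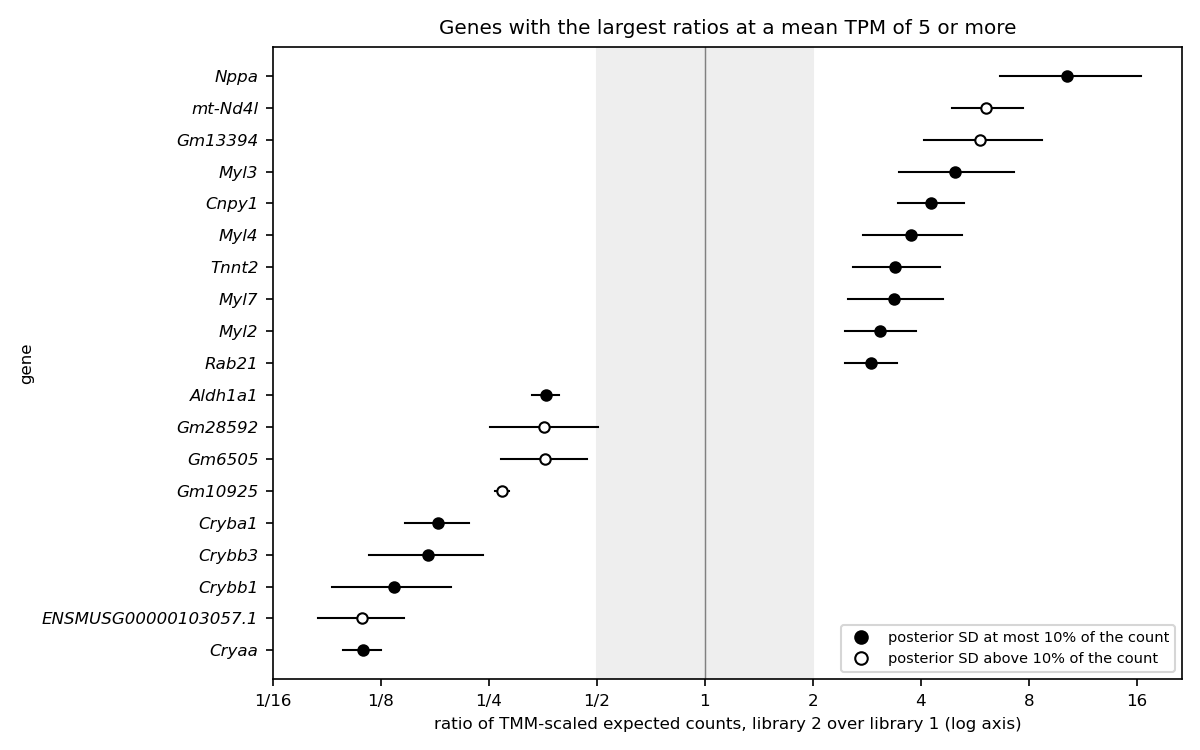
Ratio of TMM-scaled expected counts, library 2 over library 1, on a log axis for the genes with the largest ratios each way among those with a mean of at least 5 TPM, with 95% Clopper-Pearson intervals (lines), the band within 2-fold in grey, and open points where the posterior SD exceeded 10% of the count. Cryaa lies lowest among genes with assignable reads and Nppa highest at 10.2-fold, and Gm15899, with no count in library 2, is left out.

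At the level of transcripts, most genes used the same leading isoform in both pools. Of 6226 genes with at least 2 annotated transcripts and a mean of 10 TPM, 5838 (93.8%) had the same dominant transcript in both libraries. Its median share was 75.3% of the gene's TPM, against 40.1% in the 388 genes where it differed. Of 29 genes of the mesenchyme and regulator lists that met these limits, 27 had the same dominant transcript. A protein-coding transcript led for Col3a1 with 57.9% ± 1.22 of TPM (mean ± SD, n = 2), for Msx1 with 96.0% ± 0.104, for Col1a2 with 94.7% ± 0.243, for Alx1 with 93.0% ± 1.02 and for Prrx1, a homeobox gene of limb and facial mesenchyme, with 38.6% ± 0.152. For Vim the leading transcript, ENSMUST00000148248.2, is annotated as a retained intron and held 36.6% ± 0.294. The exceptions were Dlx1 and Meis2, a homeobox gene of cranial mesenchyme. For Dlx1 a retained-intron transcript led in library 1 with 46.6% (40.1% in library 2) and another retained-intron transcript led in library 2 with 51.1% (46.3% in library 1). For Meis2 a protein-coding transcript led in library 1 with 26.4% (14.6% in library 2) and another one led in library 2 with 34.5% (19.6% in library 1). Transcript shares rest on reads that isoforms share, and total RNA holds unspliced precursors that can be assigned to retained-intron transcripts.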

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

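Entries outside the main measurement, those with numeric identifiers, summed to 9 expected counts in library 1 and 6 in library 2. These sums exceed the limit of 3 counts, but that limit holds for a single entry and the sums run over 26248 entries, so they show no signal beyond it. With 2 libraries in 1 group, no library was tested for standing apart from the other, and there is no difference between groups to test.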

How the results depend on the processing

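The number of detected genes lay between 10183 at 5 TPM and 17523 with posterior mean TPM, and between 14280 and 14525 with either library left out. Counted at 0.5 TPM, 8 Hox genes were detected, and at 5 TPM 1 was, with 9 white blood cell, 3 heart and liver and 5 stress genes at 5 TPM, because the threshold itself sets the count. The other 151 counts of detected list members moved by no more than 1.5 times. As shares of expected counts in place of TPM, spike-ins held 7.27%, mitochondrial genes 1.26%, haemoglobin genes 0.596%, histone genes 0.159%, protein-coding genes 88.2% and the 10 most abundant genes 3.17%, because TPM divides by length. The coefficient of variation was 2.99% with DESeq2's gene-wise estimate, which on counts simulated at 10% gave 3.55%, and between 8.86% and 10.4% under the other alternatives. With 10 counts and no TPM filter, 1439 genes differed at least 2-fold, 565 higher in library 2 and 874 higher in library 1, and with 200 counts 61 did, 24 and 37, because the filters set how many genes enter. Limits chosen after seeing the data left 129 genes with assignable reads, 41 higher in library 2 and 88 in library 1, and 63 with the whole interval beyond 2-fold, 33 higher in library 2 and 30 in library 1. Library totals moved the scale of library 2 by 0.03 on the log2 scale against TMM and spike-in totals by 0.06, and the number of genes differing 2-fold stayed between 183 and 189 under the scalings. The median log2 ratio of heart and liver genes was 0.82 with a prior count of 5, which pulls ratios of low counts toward 0, and that of cell cycle genes was 0.056 with library totals. The other 102 list ratios moved by less than 1 SD of random list medians, and none of the 26 lists changed its side of the random range. A change of scaling moves a list and its random lists nearly alike, so only the prior count and the posterior means put that side to a check. The same dominant transcript was found in 89.97% of 9807 genes at a limit of 1 TPM and in 95.8% of 2324 genes at 50 TPM, and the cause was not tested. Leaving out a library was not possible for ratios, spread and transcript comparison, which need both.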

Other observations

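All tests and further gene lists in this part were chosen only after the results were seen. Genes of human craniofacial syndromes were transcribed in these prominences. All 10 genes of a list for mandibulofacial dysostosis and ribosome production were detected, among them the nucleolar gene Ncl (304 ± 18.1 TPM), the splicing factor genes Eftud2 (198 ± 4.82) and Sf3b4 (167 ± 11.4), and Tcof1 (27.9 ± 0.778), the Treacher Collins syndrome gene. All 10 genes of a craniosynostosis list were detected, led by Tcf12 (164 ± 13.3), the partner of Twist1 (64.9 ± 7.23). All 14 genes of a list for cleft lip or palate were detected, among them Arhgap29 (33.1 ± 3.82) and Chd7 (31.9 ± 1.05), and its median log2 ratio of -0.11 lay below the random range (-0.10 to 0.10). The medians of the mandibulofacial and craniosynostosis lists, 0.03 and -0.01, lay inside their random ranges.

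Matrix and adhesion genes were also transcribed. All 24 genes of a matrix list were detected, led by Sparc (324 ± 19.2 TPM), Fbln1 (154 ± 4.74), Lum (99.1 ± 6.75) and the fibronectin gene Fn1 (92.0 ± 0.219), and its median log2 ratio of -0.04 lay below the random range (-0.03 to 0.09). All 11 ephrin and Eph receptor genes were detected, with Efna5 at 51.1 ± 2.5 and Epha7 at 42.6 ± 0.643. Of 10 TGF-beta genes, 9 were detected, with the receptor Tgfbr1 at 81.3 ± 2.72 and the ligand Tgfb1 below the threshold at 0.770 ± 0.0424. The median log2 ratios of the ephrin and TGF-beta lists, -0.004 and -0.07, lay inside their random ranges. Smad4, the shared effector of TGF-beta and BMP signals, was 1.5-fold (1.40 to 1.60) higher in library 2. Brain region regulators, a list that holds genes chosen because they differed, went both ways, with the ventral forebrain gene Nkx2-1 2.42-fold (2.08 to 2.82) higher in library 2 and the ventral eye gene Vax2 4.11-fold (2.84 to 6.10) higher in library 1.

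Lens and pigment cell genes were higher in library 1. A lower share of facial tissue in library 1 would raise tissues from outside the face there. Skeletal muscle genes were higher in library 2, with a median log2 ratio of 0.50 (random range -0.22 to 0.12). Muscle cells may belong to the facial tissue itself, so this list cannot decide the question. The heart and liver list, of tissues outside the dissection, also lay toward library 2, at 0.99 (random range -0.33 to 0.19). Of its 12 measured members, 6 had an interval above 1 and 1 had an interval below it. For this list, with 8 of 16 members detected, the values argue against a rise of every outside tissue alike in library 1. A lower facial share that raised only some tissues stays open. Reads shared between gene copies are argued against by 90.3% of 31 members having assignable reads. More eye tissue in the pool of library 1 is a candidate source that stays open: of 26 further lens and pigment genes 16 had an interval of the ratio wholly toward library 1 and 1 toward library 2, with a median log2 ratio of -0.81 (random range -0.25 to 0.12), or -0.39 for lens and -0.98 for pigment cell genes. The most abundant were Trpm1 (17.7 ± 8.30 TPM), Cryab (10.6 ± 2.15) and Rab38 (8.67 ± 0.354), and 6 of 20 lens genes and 10 of 16 pigment cell genes were detected in both libraries, none of them in the fixed lists.

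Most heart genes were higher in library 2, while the regulators Nkx2-5 and Tbx5 and the channel gene Hcn4 had ratios below 1. More skeletal muscle alone is argued against by the 5 genes of the fixed heart and liver list that heart uses and skeletal muscle does not, whose median log2 ratio exceeded that of skeletal muscle regulators by 1.53 (2 SD of random lists, -0.51 to 0.51), though this list gave the pattern. For 5 such genes outside the fixed list the difference was 0.27 (-0.65 to 0.65) and 2 had ratios below 1, so for these it cannot be told apart from more skeletal muscle. Reads shared between gene copies are argued against by assignable reads in 100% of 24 members. Heart tissue in the pool of library 2 is a candidate source that stays open. Of 18 further heart genes, 14 had an interval wholly toward library 2 and none toward library 1. Their median log2 ratio was 0.90 (random range -0.35 to 0.20). Only the 5 genes outside the fixed list compared above were taken as unused by skeletal muscle, so this median does not separate heart from skeletal muscle. The most abundant of 20 were Tnnc1 (13.3 ± 8.16 TPM), Myh7 (3.85 ± 3.51) and Sln (3.54 ± 1.19), none of them among those 5. Of the 20, 7 were detected in both libraries and none was in the fixed lists.

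Y-linked genes were higher and Xist lower in library 2, with a median ratio of 1.27 over 4 Y-linked genes and a ratio of 0.818 for Xist. The Y-linked ratios ran from 1.15 (1.03 to 1.28) for Eif2s3y to 1.42 (1.28 to 1.57) for Uty. Tissue make-up or scaling that moves these genes whatever the sex is argued against by their X-linked partners, which the Y-linked genes exceeded by a median log2 difference of 0.26 (SD 0.13, 4 pairs). A larger share of male embryos in the pool of library 2 may be the source and stays open, since no further Y-linked gene had enough counts to test it. A share of females follows if Xist came from females alone and Y-linked genes from males alone, at 1 level per sex in both pools. The Y-linked median and the Xist ratio then imply 59.5% in library 1 and 48.6% in library 2. That is a difference of 10.8 percentage points, where drawing embryos at even odds gives an SD of 7.17. The Y-linked ratios differed between genes, so these shares depend on the gene used. With 1 group in the design, no biological difference between groups was tested for these patterns.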
